A study of Mus musculus with 8 samples.

How the data were processed

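Total RNA was measured by sequencing in 8 libraries of microglia, the resident macrophages of the brain, isolated from the corpus callosum of mice of a mixed FvB and C57BL6 background. Per the labels, the mice carried a tamoxifen-inducible Cre recombinase under Cx3cr1 and either 1 or both alleles of Qk flanked by loxP sites, received tamoxifen at 8 weeks of age and were then fed 0.2% cuprizone, a copper chelator that kills oligodendrocytes and strips myelin, for 6 weeks. The labels do not state whether each library came from a separate animal, so p-values measure only the spread between these libraries, which may be technical. Sex-linked transcripts, given at the end, point to more than 1 animal per library.

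The genotype field calls mice with 1 flanked Qk allele WT and mice with both Qk-KO, and all carried the Cre recombinase. The labels contradict each other on the genotype of 4 of the 8 libraries. By sample name and source, 4 libraries were WT and 4 were Qk-KO, each numbered 1 to 4. By the genotype field, named WT 2 and 3 were Qk-KO and named Qk-KO 1 and 3 were WT, so that each combination of name and genotype field held 2 libraries. Both groupings were therefore tested, and libraries are called by their names throughout. The rule for the leading grouping was the grouping whose recomputed log2 fold changes correlated above 0.9 with those the authors deposited. The rule did not fix the genes. Over the 14150 genes for which the authors' deposited table gives an adjusted p, r across genes was 0.917 for the sample names and -0.229 for the genotype field. Over all 22546 genes tested here it was 0.790 and -0.123, which would not have passed, and the genotype field would then have led. The first gene set was chosen after the data were seen, and on it the sample names led. Genes are not independent replicates, and these r values compare 2 computations on the same libraries.

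The deposited table held 46983 genes with versioned Ensembl identifiers. The submitters' processing notes name FastQC, HISAT2, StringTie and DESeq2 and the build mm10, with no versions or roles, and the annotation release is not given in the sources used here. The 8 library columns deposited by the authors hold values on a log2 scale, read from their behaviour as regularized log2 values that are shrunken towards the gene's mean where counts are low. Genes without reads, 19497 in number, are listed at 0. The authors' deposited column of mean normalized signal, named baseMean per the file headers, was read from its values as an average over libraries after scaling for depth. Per the file headers, the deposited table also gives the authors' log2 fold change with its standard error, a test statistic, which is a score, a p-value and an adjusted p-value. No counts per library were in the table used here, so the planned count test could not be run. The planned fallback was used: limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes, on the log2 values as deposited, with no pseudocount because the values were already logarithms. Shrinkage in the deposited values understates the changes of genes with few reads.

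Genes entered the test with reads in at least 1 library and a normalized value of at least 1 in at least 4 libraries, which left 22546 of the 27486 genes with reads, 15927 of them protein-coding. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Single scores were tested with two-sided exact permutation tests over all 70 assignments of the 8 libraries, whose smallest p is 0.0286. Expression in CPM was the authors' mean signal divided by 56.8, the signal that equals 1 CPM over the sum of all genes. Simulated log2 values for the comparison of 4 against 4 libraries covered 22546 genes, with normal noise independent between genes. Changes were placed only in genes of at least 1 CPM. Limma recovered 32.8% of genes changed by 0.5, 79.1% of those changed by 1 and 93.9% of those changed by 2 on the log2 scale. Of its 144 calls, 7 were false. These rates need not hold for the real libraries, where Ciita, H2-Aa and Adgb differed by -1.14, -1.15 and 1.16. Their limma adjusted p were 0.314, 0.365 and 0.257. A list shifted by -0.3 in simulated values of the same comparison was called, and no other list was. Because the simulated genes varied independently, this does not show how often camera calls lists by chance in the real libraries.

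The relative depth was read from genes with reads in a single library, where 8 times the mean signal is a whole multiple of what 1 read is worth in that library. Between 187 and 420 such genes per library gave whole numbers within 1% in 100% of cases. Gene by gene, the regularized values cannot be turned back into counts, so no count test was run on recovered reads. Library totals are rough estimates of reads assigned to genes. For them, the regularized values were taken off the log2 scale, summed over genes with reads and divided by what 1 read is worth. No pair of libraries was near-identical: over genes kept by the stricter filter, the closest pair still had a median absolute difference of 0.0902 on the log2 scale.

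The tests, the leading rule, the rule for named genes and the gene lists were fixed before the data were examined. The 29 gene lists covered microglial programmes, markers of other cell types and sex-linked transcripts. All 468 symbols matched the deposited table, 1 of them through an older symbol in the RefSeq gene table for GRCm38.p6. Where a symbol occurred more than once, the row with the highest mean signal was used. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the 29 lists. Results of 1 of these lists and of 1 member of another are not reported here. Gene positions are from GENCODE annotation of GRCm38, the same assembly as mm10, to which 98.9% of the identifiers matched without their versions.

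The rule for named genes took Qk, and then up to 12 genes higher and 12 lower with the largest log2 fold change among genes called, with a mean of at least 1 CPM, no overlap between the groups, and an established symbol. No gene met it in the limma fit. The rule was therefore applied to the authors' deposited fold changes and adjusted p-values, a choice made after the data were seen. In each list the members with the smallest limma p were named, up to 4 where any member was called in the authors' deposited table and up to 2 otherwise. Genes named outside the rule are marked where they appear.

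Alternatives fixed with the tests were no filter and a stricter filter, leaving out each library, the replicate number as a block, the other label as a covariate, a minimum fold of 1.2, an adjusted p under 0.10, the other grouping and the 4 libraries with agreeing labels alone. Others were added after the data were seen: other scalings, plain empirical Bayes, and adjustments for libraries that stood apart in markers of other brain cells. For these, a non-immune score was the mean of the oligodendrocyte, precursor, astrocyte, neuron, endothelial, mural and fibroblast lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.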

Results

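Microglia from the corpus callosum of mice fed 0.2% cuprizone for 6 weeks were profiled in 8 RNA libraries, 4 named WT and 4 named Qk-KO. Qk encodes the RNA-binding protein quaking, a regulator of splicing and RNA stability, and the series asks what its loss in microglia changes during demyelination. For named WT 2 and 3 and named Qk-KO 1 and 3 the genotype field of the labels states the opposite of the name, so no difference below is assigned to a genotype. Rough totals of reads assigned to genes, summed from the shrunken values, ranged from 43.9 M in named Qk-KO 3 to 69.7 M in named WT 1. Totals were 65.0 ± 4.11 M in named WT and 50.3 ± 7.09 M in named Qk-KO libraries (mean ± SD, n = 4 each). The size factors did not overlap, at 1.05 to 1.26 in named WT and 0.753 to 0.997 in named Qk-KO (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows).

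Qk, the targeted gene (ENSMUSG00000062078.14, chromosome 17, 10202601 to 10319854, minus strand, GRCm38), was abundant in every library, at a mean of 793.6 CPM. Its regularized log2 values were 15.50, 15.38, 15.41 and 15.37 in named WT 1 to 4 and 15.59, 15.40, 15.69 and 15.29 in named Qk-KO 1 to 4. By sample name, Qk was 15.41 ± 0.06 in WT and 15.49 ± 0.18 in Qk-KO (mean ± SD, n = 4 each). The difference was 0.08 ± 0.09 (SE) with a 95% interval of -0.11 to 0.27 (limma, adjusted p = 0.819). By genotype field it was 15.54 ± 0.14 in WT and 15.37 ± 0.06 in Qk-KO, a difference of -0.16 ± 0.08 (SE) with a 95% interval of -0.33 to 0.01 (limma, adjusted p = 0.9995). Neither grouping separated the libraries, and the value sums all exons of the gene, including any outside the deleted part. By the labels, WT mice also carried the Cre recombinase and 1 flanked Qk allele, so WT need not mean intact Qk. The Qk value therefore checks the labels little.

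The authors' deposited fold changes followed the sample names. For the 5232 genes whose deposited standard error was under 0.1, the difference between named groups correlated across genes with the authors' deposited log2 fold change at r = 0.9997, against 0.0460 for the genotype field. A positive value in the authors' deposited table therefore means higher in the libraries named Qk-KO.

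In the libraries named Qk-KO, genes of MHC class II antigen presentation and several genes of resting microglia were lower, while Gpnmb, Cd5l, Ms4a4a and Ms4a7 were higher, in calls of the authors' deposited table. The authors' deposited table called 173 of 14150 genes at an adjusted p under 0.05, 78 higher and 95 lower in named Qk-KO, with a median absolute log2 fold change of 0.41. Of these, 169 had no overlap between the named groups, which follows largely from their selection by the same groups. Among all 14150 genes 6.74% had none, where chance gives 2.86%. The limma fit on the regularized values was far more restrictive. It called 1 of 22546 genes, with 1863 genes at an unadjusted p under 0.05, where 1127 would be expected by chance if genes were independent and 5 of the 34 other splits of the libraries gave more. The smallest limma adjusted p among the authors' 173 genes was 0.118. Without named Qk-KO 3 limma called 0 genes (1410 at an unadjusted p under 0.05), without named Qk-KO 1 it called 2, without named WT 2 or named Qk-KO 2 it called 3, and without named Qk-KO 4 it called 7. The calls of genes below rest on the authors' deposited table unless limma is named.

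**Figure D1:**
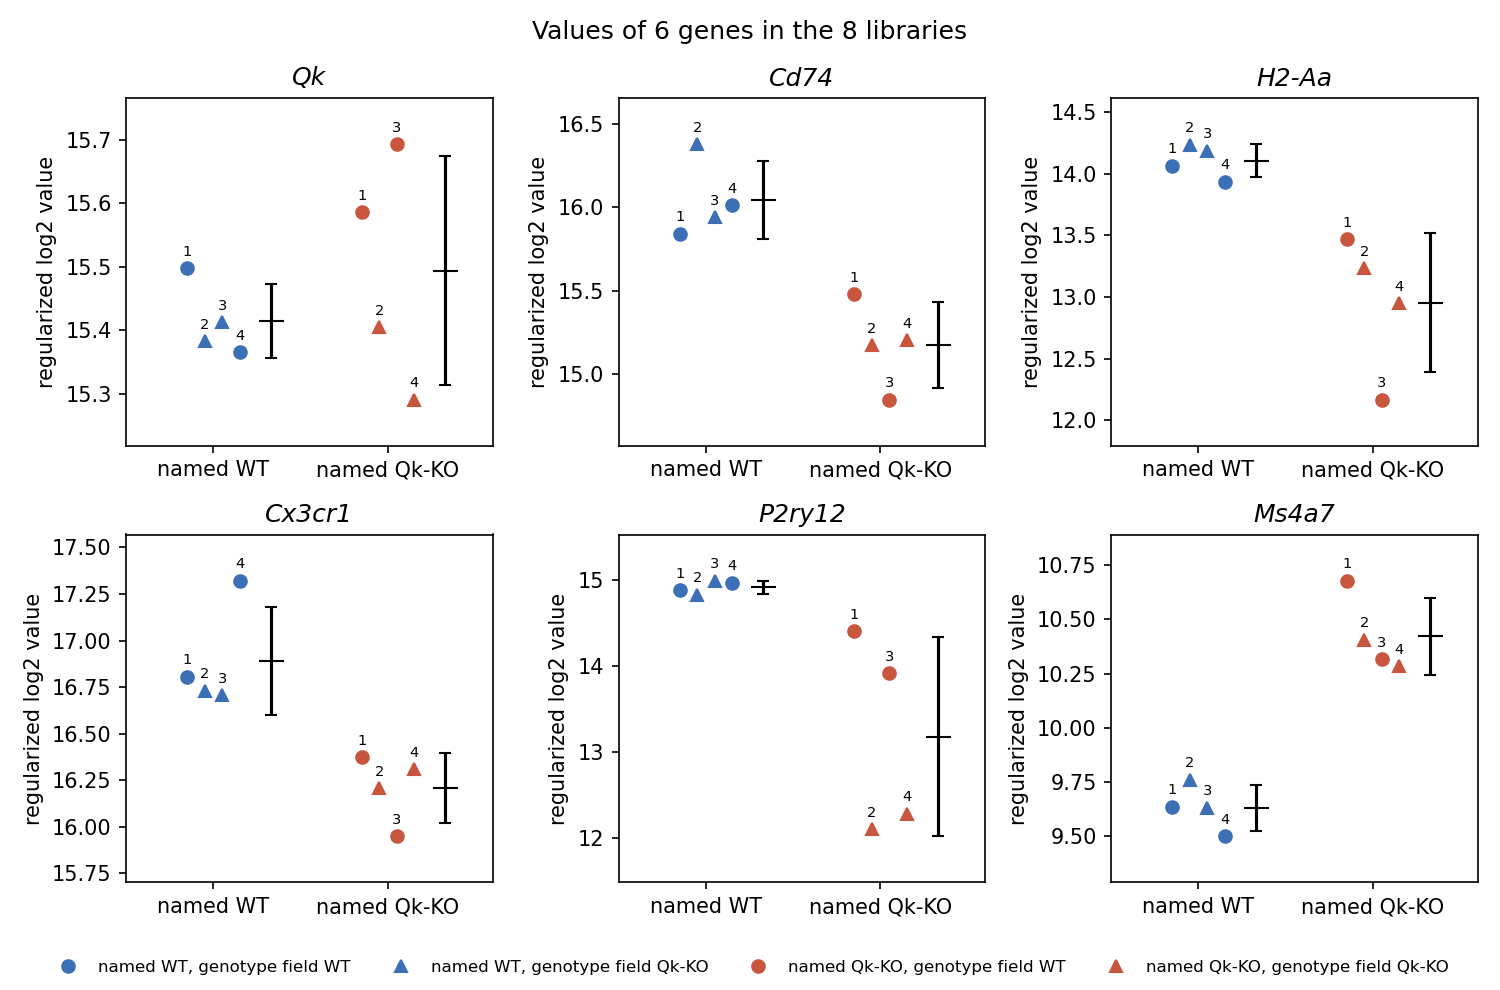
Regularized log2 values (vertical axes) of 6 genes in each library, by sample name (horizontal axis), with the replicate number above each point, circles for libraries with genotype field WT, triangles for Qk-KO, and bars for mean ± SD of 4 libraries. Cd74, H2-Aa and Cx3cr1 were lower and Ms4a7 was higher in every library named Qk-KO, Qk overlapped, and P2ry12 ranged from 12.09 to 14.40 in the libraries named Qk-KO.

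Antigen presentation genes, chiefly those of MHC class II, were lower in the libraries named Qk-KO and formed the list with the smallest camera p. Of its 18 members, 5 were called in the authors' deposited table, all lower in named Qk-KO; adjusted over the list alone, 8 were lower and 1 higher. Cd74, the invariant chain that guides MHC class II molecules to endosomes (chromosome 18, 60803848 to 60812652), was 1.83-fold lower in the authors' deposited table (log2 fold change -0.87, SE 0.15, adjusted p = 4.03e-05). The class II chains H2-Aa and H2-Ab1, both on chromosome 17, were 2.08-fold and 1.98-fold lower there, with adjusted p = 0.000524 and 0.00150. Ciita, the transcriptional master regulator of class II genes, was 2.12-fold lower in the authors' deposited table (adjusted p = 0.000731), and H2-DMa, which helps load peptides on class II and was named to complete the 5, was 1.29-fold lower (adjusted p = 0.0399). On the regularized scale Cd74 was 16.04 ± 0.24 in named WT and 15.17 ± 0.26 in named Qk-KO, and H2-Aa was 14.10 ± 0.14 and 12.95 ± 0.57 (mean ± SD, n = 4 each). The class I genes H2-K1 and B2m, members named after their values were seen, differed by -0.02 and -0.05 in limma, neither called. Camera placed the list lower (adjusted p = 6.14e-07), and the mean of its members was 13.38 ± 0.08 in named WT and 13.04 ± 0.18 in named Qk-KO (SD, n = 4 each; exact permutation p = 0.0286, and 0.276 adjusted over the 29 lists). The call was lost with an estimated correlation (adjusted p = 0.471) and with fry in a set direction (adjusted p = 0.144), while fry for changes in either direction called it (adjusted p = 0.0135). Astrocyte and endothelial markers were also lower on average in named Qk-KO, with mean differences of -0.86 and -0.50. In named Qk-KO 4, however, both lay above the named WT mean.

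Homeostatic microglia genes, which mark unstimulated microglia, were also lower. Of 16 members, 4 were called in the authors' deposited table, all lower; adjusted over the list alone, 8 were lower. Cx3cr1, the fractalkine receptor and the gene under which the Cre recombinase of these mice is expressed, was 1.62-fold lower in the authors' deposited table (adjusted p = 0.00170). Gpr34, a lysophospholipid receptor, was 1.41-fold lower (adjusted p = 0.0266), Sall1, a transcription factor of microglial identity, 1.31-fold lower (adjusted p = 8.65e-05) and Csf1r, the receptor for the survival factor of microglia, 1.21-fold lower (adjusted p = 0.00327) in the authors' deposited table. Tmem119 and Siglech, members named after their values were seen, differed by -0.08 and -0.04 in limma, neither called. The mean of the members was 15.00 ± 0.08 in named WT and 14.69 ± 0.09 in named Qk-KO (SD, n = 4 each; exact permutation p = 0.0286, and 0.276 adjusted over the 29 lists). Astrocyte, erythroid and endothelial markers were also lower on average in named Qk-KO, at -0.86, -0.66 and -0.50. In named Qk-KO 4, however, the astrocyte and endothelial means lay above those of named WT. Camera placed the list lower (adjusted p = 7.39e-06), a call lost with an estimated correlation (adjusted p = 0.471) and with fry in a set direction (adjusted p = 0.144), but not with fry in either direction (adjusted p = 0.0101). P2ry12, the purinergic receptor of resting microglia, had a difference of -1.74 ± 0.53 (SE; limma, adjusted p = 0.485), and without it, a setting chosen after the data were seen, the list's mean difference was -0.21 (camera adjusted p = 5.31e-05). Cx3cr1 spans several annotated genes, among them Gorasp1 and Csrnp1 on its own strand, so part of its reads is uncertain.

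Other microglial programmes held few called genes. Of 25 disease-associated microglia genes, induced around damaged myelin, Gpnmb was 1.67-fold higher in the authors' deposited table (adjusted p = 0.000332) and the other 24 were not called. Itgax, Ccl6 and Lpl of that list differed by -0.44, -0.36 and -0.26 in limma, and the list was not called (camera adjusted p = 0.846). Its mean difference was 0.02 and its median -0.0042; without named Qk-KO 4 it was placed higher (0.08, camera adjusted p = 0.0455), and without named Qk-KO 1 or 2 the difference was negative (-0.03 and -0.01). Among 40 genes of phagocytosis, Stab1, a scavenger receptor, was 1.36-fold higher and Cd36, another scavenger receptor, 1.51-fold lower in the authors' deposited table (adjusted p = 0.000397 and 0.000226), and fry found changes in either direction (adjusted p = 0.00679) while camera did not call the list (adjusted p = 0.111; -0.10 and 0.0138 without named Qk-KO 1). Ctss, a lysosomal protease that trims the invariant chain, was 1.26-fold lower in the authors' deposited table (adjusted p = 0.0310) and the only one called of 36 lysosomal genes. The lysosomal list was not called (camera adjusted p = 0.0621), but was placed lower without named WT 2, named Qk-KO 1 or named Qk-KO 2 (adjusted p = 0.0412, 0.0176 and 0.00933).

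Complement genes were lower as a list by camera (adjusted p = 0.000177), with all 15 members at negative differences, none of them called in the authors' deposited table over all genes and 4 lower adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.471) and with fry in a set direction (0.144), but not with fry in either direction (0.0466). Cfb and C2 differed by -0.53 and -0.41 in limma (adjusted p = 0.443 and 0.471). The mean of the list had an exact permutation p of 0.0571 (0.414 adjusted over the 29 lists). Astrocyte, erythroid and endothelial markers were also lower on average in named Qk-KO, at -0.86, -0.66 and -0.50. Named Qk-KO 4 was an exception, with astrocyte and endothelial means of 10.28 and 9.99, against 9.55 and 9.58 in named WT. Cholesterol biosynthesis, fatty acid synthesis and type I interferon response genes were placed lower by camera (adjusted p = 0.00394, 0.00430 and 0.0155), with mean differences of -0.15, -0.26 and -0.12, calls lost with an estimated correlation (adjusted p = 0.712, 0.634 and 0.833). Sqle, Hmgcs1, Scd2, Fads1, Rsad2 and Oasl2 of these lists differed by -0.66, -0.27, -0.33, -0.30, -0.24 and -0.30 in limma. Cell cycle genes were placed higher (adjusted p = 0.0291, mean difference 0.12), with Mcm2 and Mcm4 at 0.20 and 0.18, a call also lost with an estimated correlation (adjusted p = 0.833). Leaving out 1 library ended the call of cholesterol biosynthesis for named Qk-KO 3 (adjusted p = 0.0569), of cell cycle for named WT 3 (0.276) and of the interferon list for named WT 3, named WT 4 and named Qk-KO 1, 2 and 4 (0.329, 0.111, 0.167, 0.0794 and 0.0561). Without named Qk-KO 4 the cell cycle difference was -0.01. No member of these 5 lists was called in the authors' deposited table. The lists for cholesterol efflux, fatty acid oxidation, inflammatory cytokines and the immediate early response differed by 0.02, -0.02, 0.10 and 0.05 and were not called (camera adjusted p = 0.532, 0.733, 0.234 and 0.673), although fry in either direction called fatty acid oxidation (adjusted p = 0.0466). Without named Qk-KO 4 cholesterol efflux and inflammatory genes were placed higher (adjusted p = 0.0279 and 0.00612), the latter also without named Qk-KO 2 (0.0463). The inflammatory difference turned negative without named WT 4 or named Qk-KO 1 (-0.04 and -0.06), and that of cholesterol efflux without named Qk-KO 1 or 2 (-0.0004 and -0.01). Single left-out libraries also turned the signs of fatty acid oxidation and the immediate early response.

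**Figure D2:**
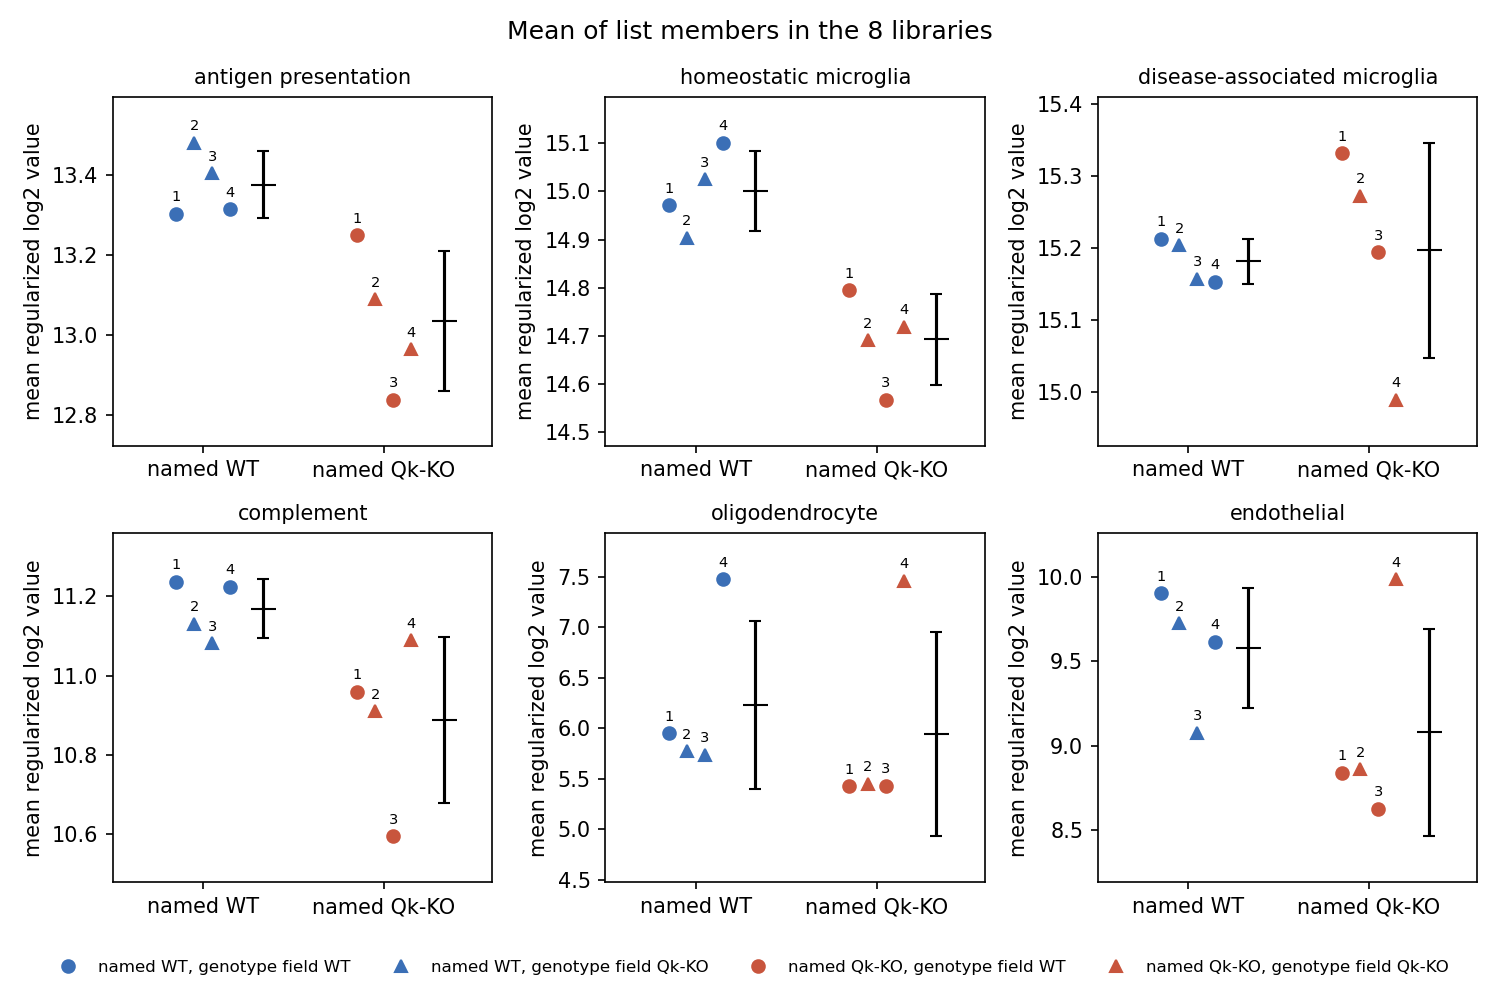
Mean regularized log2 value of the members of 6 lists (vertical axes) in each library, by sample name (horizontal axis), with replicate numbers, circles for genotype field WT, triangles for Qk-KO, and bars for mean ± SD of 4 libraries. Antigen presentation and homeostatic microglia means did not overlap between the named groups, while oligodendrocyte markers were highest in named WT 4 and named Qk-KO 4, at 7.48 and 7.46.

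Markers of several other cell types were lower in named Qk-KO. Mean differences were negative for 12 of 13 such lists. Named Qk-KO 4 nevertheless had the highest endothelial and mural and fibroblast means of the 8 libraries, at 9.99 and 7.17. Camera placed astrocyte (-0.86), erythroid (-0.66), mural and fibroblast (-0.52), endothelial (-0.50), oligodendrocyte precursor (-0.50), choroid plexus and ependymal (-0.49) and neuron (-0.40) markers lower in named Qk-KO, with adjusted p = 0.000724, 0.000444, 0.00475, 0.00209, 0.0292, 0.00779 and 0.0110. None was called with an estimated correlation (smallest adjusted p = 0.661), and their exact permutation p ranged from 0.0857 to 0.371. Slc1a3 of astrocytes, Cldn5 of endothelium and Hba-a1 of red cells differed by -0.46, -0.73 and -0.67 in limma, none called, and all 5 erythroid genes were lower in the authors' deposited table adjusted over the list alone. Without named Qk-KO 3 the precursor, neuron and mural lists were no longer called (adjusted p = 0.228, 0.154 and 0.0830). The precursor list also lost its call without named WT 4, named Qk-KO 1 or 2 (0.301, 0.0853 and 0.0986), and the neuron list without named WT 4 or named Qk-KO 2 (0.101 and 0.0748). The oligodendrocyte list differed by -0.29 (camera adjusted p = 0.348), with -0.80 and a call (0.000959) without named Qk-KO 4, and 0.12 without named WT 4. The monocyte and neutrophil lists differed by -0.12 and -0.37 (camera adjusted p = 0.454 for each). They were called lower without named WT 4 (0.0150 and 0.00117) but turned positive without named WT 2, at 0.17 and 0.45, and the monocyte list also without named Qk-KO 4 (0.08). T and NK cell, B cell and border-associated macrophage lists differed by -0.03, 0.00 and -0.05 (camera adjusted p = 0.769, 0.846 and 0.872), the first with a positive median and the second with a test direction below 0, and single left-out libraries turned the sign of each. Ms4a7 was the only border-associated macrophage marker called in the authors' deposited table. Sex-linked transcripts differed by -0.12 (camera adjusted p = 0.605, and a difference of 0.14 without named Qk-KO 1). This list joins Xist with Y-linked genes, so its mean cannot measure the mix of sexes. Xist differed by 0.48 and the Y-linked Kdm5d by -0.34 in limma, neither called.

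Among the genes taken by the fixed rule, the highest log2 fold change in the authors' deposited table was that of Adgb, which encodes androglobin (1.26, SE 0.24, adjusted p = 0.000156). Ms4a4a and Cd5l, a secreted macrophage protein, followed at 1.12 each (adjusted p = 0.00610 and 8.71e-05). Ms4a7, a membrane protein of macrophages, had the smallest adjusted p of the 24, 2.72e-08, with a log2 fold change of 0.82 and an SE of 0.12 in the authors' deposited table. Its values were 9.63 ± 0.11 in named WT and 10.42 ± 0.18 in named Qk-KO libraries (SD, n = 4 each). The semaphorin receptor Plxna1 and the netrin receptor Unc5a were higher by 0.92 and 0.90 in the authors' deposited table. Gpr31b, Aoah, which inactivates endotoxin, Rgs1, a regulator of G-protein signalling, Nme4, Trp53i11 and Gpnmb were higher there by 0.93, 0.83, 0.81, 0.76, 0.75 and 0.74. Besides the class II genes, the authors' deposited table had Nos1 at -1.13, Palld at -0.95, the G-protein coupled receptor Gpr83 at -0.93, the interferon-gamma-induced chemokine Cxcl9 at -0.89, the chromatin remodeller Chd5 at -0.84, Tnfrsf17 at -0.81 and Chst8 at -0.80. Mir5107, at -0.98 in the authors' deposited table, lies at 60812076 to 60812163 on chromosome 18, inside Cd74 and on the same strand, so reads of the 2 genes cannot be told apart.

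**Figure D3:**
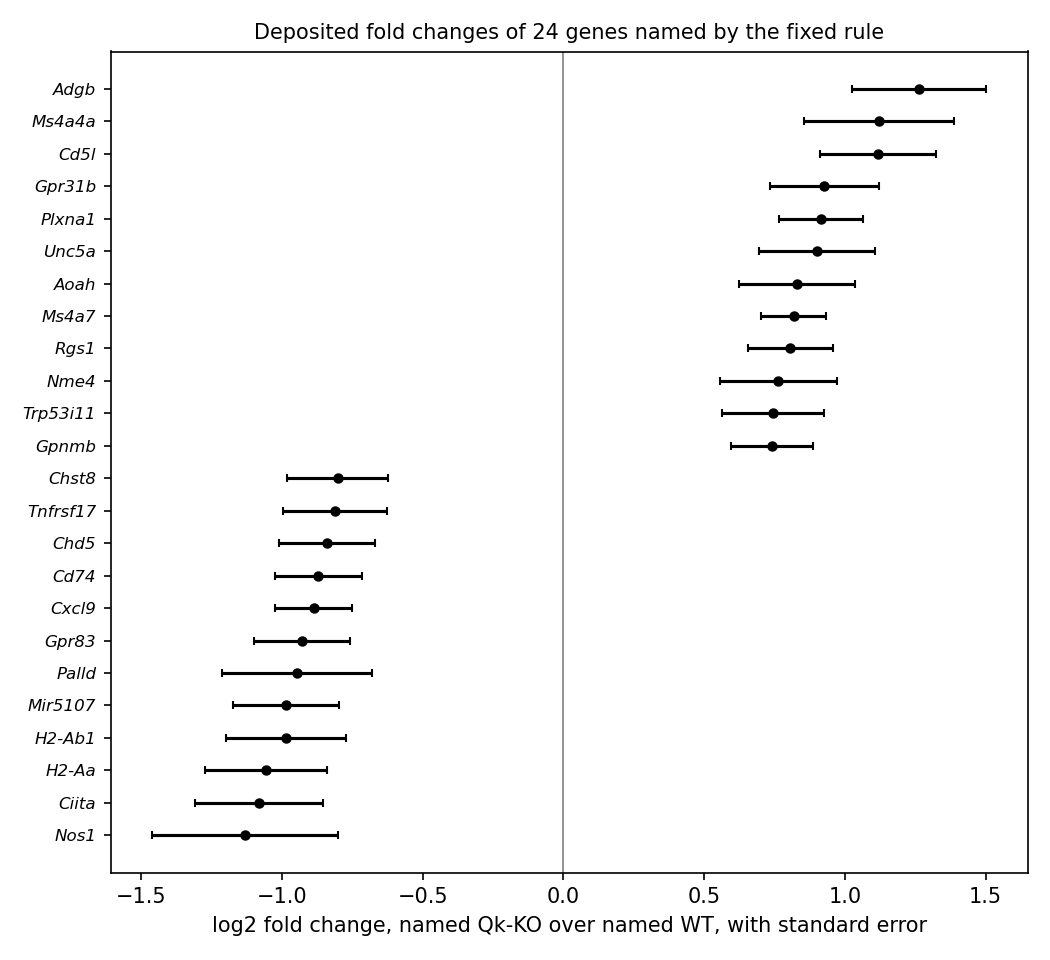
Log2 fold change from the authors' deposited table, named Qk-KO over named WT (horizontal axis), with its standard error as bars, for the 24 genes taken by the fixed rule (vertical axis). The values run from -1.13 for Nos1 to 1.26 for Adgb, and Ciita, H2-Aa, H2-Ab1 and Cd74 lie between -1.08 and -0.87.

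The gene called by limma was C1qtnf5 (chromosome 9, 44107245 to 44109187), named outside the rule since it lay under 1 CPM. Its values were 4.96 ± 0.40 in named WT and 2.35 ± 0.05 in named Qk-KO (SD, n = 4 each), a difference of -2.62 (limma, adjusted p = 0.00612), against a log2 fold change of -4.32 in the authors' deposited table, which gives no adjusted p for it. The named Qk-KO values of 2.29 to 2.41 rose as the size factor fell, as for genes with few or no reads, so shrinkage limits the limma difference and the SD of 0.05. C1qtnf5 lies inside Mfrp on the same strand, so the division of reads between the 2 genes is uncertain. The call was lost with the stricter filter, which removes the gene.

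By the genotype field, limma called 0 genes, with 602 at an unadjusted p under 0.05, and 1 gene without named WT 1, named WT 4 or named Qk-KO 2. The antigen presentation and homeostatic microglia lists, with mean differences of 0.06 and -0.02, were not called in this grouping (camera adjusted p = 0.188 and 0.555). Border-associated macrophage and neutrophil markers were placed higher (mean differences 0.30 and 0.96, camera adjusted p = 0.000397 for each) and inflammatory cytokine genes lower (-0.18, camera adjusted p = 0.0351) in libraries with the genotype field Qk-KO. None of the 29 lists reached an exact permutation p under 0.05, the smallest being 0.200. Named WT 2 held the highest neutrophil mean, 9.52, against 5.15 to 7.30 in the other libraries.

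In the 4 libraries whose labels did not conflict, 2 WT and 2 Qk-KO, limma called 3 genes, all lower in Qk-KO, and 957 had an unadjusted p under 0.05, where 1127 would be expected by chance. All 3 were named after their values were seen. P2ry12 was 14.92 in WT and 12.19 in Qk-KO, a difference of -2.74 ± 0.09 (SE; limma, adjusted p = 0.0111). In the remaining libraries it was 14.82 and 14.99 in named WT 2 and 3, and 14.40 and 13.91 in named Qk-KO 1 and 3. P2ry12 (chromosome 3, 59216272 to 59262871, minus strand) lies inside Med12l on the opposite strand, and no strand setting is given in the sources used here. Med12l was 10.28 and 10.74 in named WT 1 and 4, and 10.30 and 10.32 in named Qk-KO 2 and 4. These values argue against a move of P2ry12 reads to Med12l in these libraries. Other effects of the overlap stay open. The mitochondrial gene mt-Nd3 and Purb, a nucleic acid binding protein, differed by -9.28 and -7.75 (limma, adjusted p = 0.0111 and 0.0275), but their low level was shared by all 4 remaining libraries, at 1.92 to 3.09 for mt-Nd3 and at 1.65 to 1.998 for Purb, and so followed neither label. The count of called genes was 0 with no filter on low values and 8 with median centring. It was also 0 without named WT 1, named WT 4 or named Qk-KO 4, where 1 library was assumed to vary like the pair it was compared with.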

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

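The tests on other cells with MHC class II, on the microglial share of the RNA, on depth for the ribosomal protein genes and on other splits for the counts of genes were chosen after the results were seen. The non-immune score as a covariate and the other scalings were also added after the data were seen. A search covered 108 groups of 4 values for a library far from the other libraries of its named group, of which 5.4 would stand apart by chance. The search found 3. Oligodendrocyte markers had a mean of 7.48 in named WT 4, against 5.74 to 5.95 in the other named WT libraries, and of 7.46 in named Qk-KO 4, against 5.43 to 5.45. Neuron markers had a mean of 5.73 in named WT 4, against 5.10 to 5.16.

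Antigen presentation genes were lower in named Qk-KO (mean difference -0.34). Cells of non-immune brain tissue were argued against, since the difference with their score as a covariate was -0.36 (SE 0.11). A shift shared by genes of like expression was argued against by the list's median, at percentile 0.01 of expression-matched random lists. Genes of such random lists need not vary together. The neutrophil and sex-linked lists reached percentiles 0.04 and 0.07, with exact permutation p = 0.771 and 0.886. Depth itself stays open, since the size factors of the named groups did not overlap. Fewer dendritic cells, border-associated macrophages or B cells were argued against for the 7 MHC class II genes, which differed from the markers of those cells by -0.80 (SE 0.23). Only markers of at least 1 CPM were used: 4 of 7 for dendritic cells, 9 of 9 for border-associated macrophages and 4 of 8 for B cells. Of the macrophage markers, Ms4a7 was higher and the other 8 were lower, with a median of -0.125. Chance could not be excluded, since 2 of the 35 splits of the libraries gave a camera p as small (real 2.12e-08, smallest of the others 3.71e-10), and whether the names or the genotype field give the genotype stays open.

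Homeostatic microglia genes were lower in named Qk-KO (mean difference -0.31). A microglial share of the RNA lost to non-immune brain cells would raise their markers, but 12 of 13 lists of other cell types had negative mean differences. Those of non-immune brain cells ran from -0.86 (astrocyte, SE 0.66) to -0.29 (oligodendrocyte, SE 0.66). With the non-immune score as a covariate the homeostatic difference stayed at -0.27 (SE 0.07). These values argue against a share lost to non-immune brain cells. A share lost to other cells stays open. Homeostatic genes differed from disease-associated microglia genes by -0.32 (SE 0.10), but the latter went both ways. The medians of these lists differed by -0.15, where the SD of the disease-associated members was 0.22. A shift shared by genes of like expression was argued against by a median at percentile 0 of expression-matched random lists. Genes of such random lists need not vary together. The interferon and astrocyte lists also reached percentile 0, with exact permutation p = 0.314 and 0.229. Such a percentile can thus arise without a separation of the named groups. Depth itself stays open, since it differed with the names. Non-immune brain cells were argued against by a difference of -0.27 (SE 0.07) with their score as a covariate. Of the 35 splits, 1, the real one, gave a camera p as small (5.09e-07), but the smallest of the others was close, at 7.90e-07. A contradiction in the labels stays open too, so an effect of the genotype on these genes may be named only as a hypothesis.

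Ribosomal protein genes, noticed after the data were seen, were higher in named Qk-KO in 76 of 79 cases, with a mean of 14.04 ± 0.09 in named WT and 14.20 ± 0.04 in named Qk-KO (SD, n = 4 each; exact permutation p = 0.0286). Under the other grouping the difference was 0.048 (exact permutation p = 0.571), and without both libraries numbered 4 it was 0.146 (0.1, the smallest that 3 against 3 allows). A shift shared by genes of like expression and like exon length over all transcripts was argued against. The median of 0.169 lay at percentile 100 of random lists matched on both, most of which lay from -0.018 to 0.047. It also lay at percentile 100 of random lists matched on expression alone. Genes of such random lists need not vary together. The length of the transcript expressed was not matched, so an effect of that length stays open. Depth itself stays open here too, since it differed with the names. The authors' scaling was argued against by the smallest difference over 3 other scalings, 0.113 (SE 0.0340), although under median centring the exact permutation p was 0.0857. Non-immune brain cells were argued against by a difference of 0.124 (SE 0.0400) with their score as a covariate. The label conflict stays open, and no biological explanation was tested.

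For the count of genes by sample name, 7 of the 35 splits gave as many (real 1, highest other 121). On genes at an unadjusted p under 0.05 the names ranked 6 of 35 (real 1863, highest other 3590). By the genotype field the real count was 0, which all 35 of 35 splits reach whatever the data (highest other 121), so nothing follows from it. For the number of lists called, 13 of 35 splits gave as many (real 14, highest other 19). Chance could not be excluded for the count of genes by sample name or the number of lists. The split with 121 genes, named WT 1, 2 and 4 with named Qk-KO 4 against the rest, points to a structure of the samples: 9 of 11 endothelial markers were among its genes.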

How the results depend on the processing

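Scalings, plain empirical Bayes, the non-immune score as covariate, leaving out both libraries numbered 4 and the list without P2ry12 were chosen after the data were seen. Alternatives fixed with the tests that need counts (other size factors, upper quartile, voom, DESeq2 or a count test on recovered reads) and other pseudocounts were not run, and the authors' deposited table stands in for DESeq2. Depth differed with the names, and shrinkage limits what genes with few reads can show. The cause of the changes below was not tested, except where fewer genes or libraries entered. Genes called by sample name numbered 0 with the stricter filter, 2 with the non-immune score as covariate, 4 without both libraries numbered 4, 3 with agreeing labels only, 0 under the other grouping and 173 in the authors' deposited table, and 0 to 7 when each library was left out. By genotype field the count was 1 without both libraries numbered 4, 3 with agreeing labels only, 1 under the other grouping, and 0 to 1 when each library was left out. With agreeing labels it was 0 with no filter, 1 with the stricter filter, 5 at an adjusted p under 0.10, 7 with quantile normalization, 8 with median centring and 0 to 2 when each library was left out. Lists called numbered 3 under the other grouping, 0 with an estimated correlation, 0 with fry in a set direction and 10 to 16 when each library was left out. Fry for changes in either direction called 5: homeostatic microglia, phagocytosis, fatty acid oxidation, antigen presentation and complement. Homeostatic microglia (-0.31) and antigen presentation (-0.34) lost their calls with an estimated correlation and with fry in a set direction, and homeostatic microglia (-0.02) under the other grouping; over single libraries left out they ranged from -0.34 to -0.27 and from -0.41 to -0.27, Qk from 0.01 to 0.15. Of 552 values of the 24 named genes under alternatives, 18 reversed, all under the other grouping.

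The labels do not state that a replicate number marks a shared origin. Deviations of same-numbered libraries correlated across genes at 0.052, 0.134, 0.362 and 0.546 for numbers 1 to 4, and 3 of 4 named WT and 3 of 4 named Qk-KO libraries correlated best with their own number. The bar for pairing, over 0.1 for every number, was missed by number 1, so the libraries were treated as sharing only a number. With the replicate block the count of genes was 1 by sample name (2924 at an unadjusted p under 0.05) and 3 by genotype field (839), and 16 lists were called. No paired analysis was possible for agreeing labels only because those groups share only number 4.

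The 2 groupings cross evenly, with 2 libraries in each combination, so a sign under one does not bear on the other. Among the genes that reversed, all but Qk differed by less than their SE under the other grouping. Under the other grouping of labels the difference reversed for Qk (-0.16), Adgb (-0.25), Ms4a4a (-0.28), Gpr31b (-0.27), Plxna1 (-0.075), Unc5a (-0.018), Aoah (-0.010), Ms4a7 (-0.012), Nos1 (0.11), Ciita (0.038), H2-Aa (0.24), H2-Ab1 (0.10), Mir5107 (0.066), Gpr83 (0.028), Cxcl9 (0.20), Cd74 (0.13), Chd5 (0.021), Tnfrsf17 (0.15) and Chst8 (0.21). Lists that reversed there were disease-associated microglia (-0.067), cholesterol efflux (-0.00064), inflammatory cytokines (-0.18), antigen presentation (0.058), complement (0.049), oligodendrocyte (0.033), oligodendrocyte precursor (0.073), astrocyte (0.070), neuron (0.090), endothelial (0.17), mural and fibroblast (0.30), border-associated macrophage (0.30), monocyte (0.23), neutrophil (0.96), T and NK cell (0.15), erythroid (0.046), choroid plexus and ependymal (0.27) and sex-linked transcripts (0.20). With agreeing labels only, Qk (-0.084), disease-associated microglia (-0.052), inflammatory cytokines (-0.076), border-associated macrophage (0.26), monocyte (0.11), neutrophil (0.59), T and NK cell (0.12) and sex-linked transcripts (0.080) reversed. With the non-immune score as covariate, disease-associated microglia (-0.047), cholesterol efflux (-0.019), inflammatory cytokines (-0.11), the immediate early response (-0.15), oligodendrocyte (0.39), oligodendrocyte precursor (0.084), border-associated macrophage (0.041) and B cell (-0.12) did. The oligodendrocyte and oligodendrocyte precursor lists are part of that score, so nothing follows from their reversal. Quantile normalization reversed disease-associated microglia (-0.024), cholesterol efflux (-0.0041) and T and NK cell (0.062), and cyclic loess normalization the same lists (-0.023, -0.00010 and 3.4e-05). Median centring reversed lysosome (0.032), fatty acid oxidation (0.056), border-associated macrophage (0.030) and T and NK cell (0.047). The B cell list reversed with the stricter filter (-0.088) and without both libraries numbered 4 (-0.12). When each library was left out, ranges that crossed 0 were disease-associated microglia -0.030 to 0.084, cholesterol efflux -0.012 to 0.059, fatty acid oxidation -0.053 to 0.016, inflammatory cytokines -0.058 to 0.26, the immediate early response -0.084 to 0.17, cell cycle -0.011 to 0.20, oligodendrocyte -0.80 to 0.12, border-associated macrophage -0.18 to 0.085, monocyte -0.39 to 0.17, neutrophil -1.004 to 0.45, T and NK cell -0.22 to 0.11, B cell -0.16 to 0.12 and sex-linked transcripts -0.26 to 0.14. Ranges that kept their sign were astrocyte -1.38 to -0.47, erythroid -0.82 to -0.43, mural and fibroblast -0.90 to -0.31, endothelial -0.80 to -0.35, oligodendrocyte precursor -0.93 to -0.18, choroid plexus and ependymal -0.72 to -0.36 and neuron -0.67 to -0.24. Those of complement, cholesterol biosynthesis, fatty acid synthesis and the interferon list were -0.35 to -0.18, -0.23 to -0.095, -0.34 to -0.17 and -0.20 to -0.066.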

Other observations

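Genes of the Ms4a family, membrane proteins of blood cells and macrophages, were noticed after the data were seen. Of 12 tested, 10 had a positive difference between named Qk-KO and named WT libraries, but the family was chosen because some of its genes were already seen to be higher, so a test of the family as a set would be circular and none is given. The authors' deposited table called 3 of them, Ms4a4a, Ms4a7 and Ms4a6c, all higher, with Ms4a6c at a log2 fold change of 0.37.

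Of 13463 genes with a mean of at least 1 CPM, 59 had a gap of over 3 on the log2 scale between neighbouring libraries in order of their values, among them 12 of 14 mitochondrial genes. The regularized value of mt-Co1 was 18.00, 18.03 and 17.87 in named WT 2, named WT 3 and named Qk-KO 4 and 2.96 to 3.53 in the other libraries. That of mt-Atp6 was 14.17, 12.002, 13.90 and 14.13 in named WT 3 and named Qk-KO 1, 2 and 3, and 2.86 to 3.32 in the others. Another annotated gene overlapped 76.8% of those genes with a known position and 56.6% of the rest (Fisher's exact test, p = 0.00262).

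Transcripts of both sex chromosomes were present in every library, with Xist from 13.24 to 15.90 and the Y-linked Ddx3y from 9.96 to 11.79 on the regularized log2 scale. Xist marks female and Ddx3y male cells, so each library probably held RNA of more than 1 animal. The mix differed: Xist and Ddx3y were 15.90 and 9.96 in named Qk-KO 1, and 13.24 and 11.79 in named Qk-KO 4. Whether libraries shared animals stays open.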
